A study of Arabidopsis thaliana with 5 samples.

How the data were processed

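The samples were 5 Affymetrix ATH1 arrays of sorted BRL3-domain cells from Arabidopsis root tips, 3 of control and 2 of BL-treated seedlings, with group and replicate number taken from the sample titles and treatment labels. The deposited table holds log2 expression values that the authors made with RMA, per the submitters' processing notes, which name R 4.1.1, affy 1.70.0 and limma 3.48.3. RMA subtracts background, quantile normalizes the arrays and summarises the probes of a probe set by median polish. The base of the logarithm is not given in the sources used here and was taken as 2 from RMA and the range of the values. Scanner files were not used here, so background correction and summarisation were kept as they were. Median polish gives tied values when arrays are few: 44.7% of the probe sets had a value shared exactly by 2 or more arrays, and 121 had no residual spread at all. The labels do not say whether replicates came from separate batches of seedlings, so p-values measure only the spread between these arrays, which may be technical.

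Gene names came from the platform annotation given with the table, updated by locus through a RefSeq gene table of assembly TAIR10.1, which was used for names only. No coordinates are printed, since the array values name no genome build. Of the 22746 probe sets left after 64 control probe sets were set aside, 13513 name 1 gene, 503 several and 8730 none in that annotation. A probe set that names several genes or none is unnamed here, which does not mean that it has no gene. The locus of 13436 of the 13513 was in the reference table and that of 77 was not. For a gene with several probe sets, the one with the highest mean over the 5 arrays was used.

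The comparison of BL with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 5 arrays, treatment as the only term), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05 on the adjusted p. A descriptive count of probe sets with an unadjusted p under 0.01 and a fold of at least 1.5 stood beside it. The model had 3 residual degrees of freedom and 1.22 prior degrees of freedom. The median SD of a probe set was 0.264 over the controls and 0.0816 over the BL arrays. Gene lists of brassinosteroid, hormone, cell cycle, cell wall, stress, stem cell niche and root cell type genes were tested where at least 3 members had a single-gene probe set, with limma camera (preset correlation 0.01, then an estimated correlation) and fry.

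The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each direction, the 12 genes with the largest differences among those past the adjusted threshold whose BL values all lie on 1 side of the control values. As no gene passed, both directions were filled with the smallest unadjusted p among single-gene probe sets with that separation and a fold of at least 1.5. It adds 14 brassinosteroid and stem cell genes whatever their values, up to 4 members per list that pass adjusted over the list alone, or otherwise the 2 with the smallest p. It also adds any probe set past the adjusted threshold if 5 or fewer pass. As applied, the 2 list members with the smallest p were named even where only the first of them passed. WRKY53 is therefore named beside STZ.

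The fit was tested on simulated data for the comparison of BL with control, with 22746 probe sets at the observed spread and 50 changed at each size. At an adjusted p under 0.05 it recovered 12% of the changes of log2 1, 64% of 2, 78% of 3 and 94% of 4, with 8 false calls. With the spread scaled to that of the BL arrays it recovered 82% of the changes of log2 1, with 10 false calls. The simulated noise was independent and, for a given probe set, of equal size on all arrays. The real arrays differ in spread and hold a batch, so these rates need not apply to them. Alternatives changed the block, the filter on dim probe sets, the floor, the normalization between arrays, the variance model, array weights, the test, the thresholds and the arrays left out. A term for controls 2 and 3, a fit without these arrays, families read from gene symbols, and lists of pectin-modifying, peroxidase and root hair genes were added after seeing the data. The result of 1 of these families is not reported here. In the ordinary linear model without eBayes, the 121 probe sets without residual spread were not tested. When they were tested, that model called 1 probe set, which was among the 121. This exclusion was also chosen after seeing the data.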

Results

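Transcript levels were measured in root cells of Arabidopsis thaliana in which the promoter of BRL3, a gene for a brassinosteroid receptor, was active. The seedlings carried a yellow fluorescent protein targeted to the nucleus under that promoter. They were 6 days old and spent 2 h in liquid medium with 10 nM brassinolide (BL), the most active natural brassinosteroid, or with ethanol as the mock control. Primary root tips were then digested to protoplasts, fluorescent cells were collected by fluorescence-activated cell sorting, and their RNA was hybridised to Affymetrix ATH1 arrays. There were 3 control arrays (replicates 1 to 3) and 2 BL arrays (replicates 1 and 2). The table held 22810 probe sets as log2 expression values between 2.99 and 14.1, and the median of an array lay between 5.57 and 5.66. The number of arrays limits the precision of every comparison.

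The arrays did not all resemble each other to the same degree. Across probe sets, which are not independent replicates, the Pearson correlation between the 2 BL arrays was 0.992. Control replicate 1 correlated with the BL arrays at 0.969 and 0.974, and control replicate 2 correlated with the other arrays at 0.898 to 0.915. The first principal component held 56.9% of the variance and set control replicate 2 apart, and the second held 24.6% and set control replicate 3 apart. The poly-A spike-in probe sets, which report bacterial transcripts added to a sample before labelling, had 3' medians of 8.31 in control replicate 2 and 7.64 in control replicate 3. The same medians were 4.72 in control replicate 1, 4.53 in BL replicate 1 and 4.76 in BL replicate 2. Controls 2 and 3 were therefore treated as a batch, which holds control arrays only, with control replicate 1 and the BL arrays as the other. For that reason the difference between the BL mean and control replicate 1 is given below as the within-batch value. The hybridisation spike-in probe sets, another set of added controls, had medians of 10.48 in control replicate 2 and 9.41 in control replicate 3. Their medians were 8.49 in control replicate 1, 8.02 in BL replicate 1 and 7.68 in BL replicate 2. Every control, replicate 1 included, thus lay above both BL arrays, so the within-batch values may also hold a technical difference. The mean 3' minus 5' log2 value of the Arabidopsis actin, GAPDH and ubiquitin probe sets, a measure of RNA integrity and labelling length, was 3.31 ± 0.0304 (SD, n = 2) with BL and 3.38 ± 0.152 (SD, n = 3) in controls. This difference of -0.07 was within the spread between arrays (exact permutation test, two-sided, p = 0.7, with 0.1 the smallest p that the 10 splits allow).

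**Figure D1:**
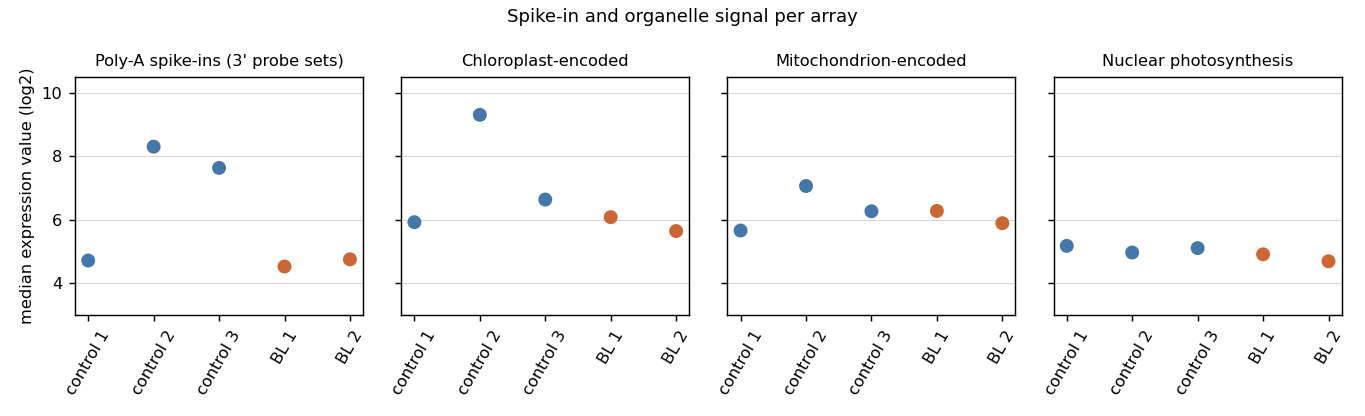
Median log2 expression value of 4 groups of probe sets on each of the 5 arrays, with controls in blue and BL arrays in orange, 1 point per array. The poly-A spike-in medians of control replicates 2 and 3 were 8.31 and 7.64 against 4.53 to 4.76 on the other arrays, and the chloroplast-encoded median was 9.31 in control replicate 2 against 5.65 to 6.64 elsewhere.

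The comparison the study was built on asks which genes of BRL3-domain cells differ after 2 h of BL. AT2G43890, of the polygalacturonase family, was at 7.10 ± 0.00212 with BL (SD, n = 2) against 4.19 ± 0.379 in controls (SD, n = 3), a log2 difference of 2.92 ± 0.25 (SE) and a fold of 7.54. AT5G51500, of the pectin methylesterase family, differed by 2.94 ± 0.267, and AT1G57590, of the pectin acetylesterase family, by 2.15 ± 0.251. On the lower side, the class III peroxidase genes AT1G71695 and AT4G33420 differed by -2.57 ± 0.156 and -2.15 ± 0.301, and the subtilase gene ATSBT5.2 by -2.74 ± 0.185. Another class III peroxidase gene, AT4G11290, named after its value was seen, differed the other way, by 3.17 ± 0.673. None of these differences passed the test over all probe sets, so they are values and not calls.

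limma with Benjamini-Hochberg adjustment called 0 of 22746 probe sets at an adjusted p under 0.05, and the smallest adjusted p was 0.168. At an unadjusted p under 0.05 there were 1616 probe sets, where 1137.3 would be expected by chance. At an unadjusted p under 0.01 there were 396 against 227.46 by chance, and 356 of them also had a fold of at least 1.5, of which 194 were higher and 162 lower with BL. Of these 356, 175 have a single gene name in the annotation, 97 higher and 78 lower. The BL values lay wholly above or wholly below the control values for 4800 probe sets, or 21.1%. Chance alone gives 20% where no values are tied, and less with the tied values described above. With a term for the batch of controls 2 and 3, limma again called 0 probe sets after Benjamini-Hochberg adjustment (smallest adjusted p 0.514), with 1839 at an unadjusted p under 0.05. That model had 412 at an unadjusted p under 0.01 with a fold of at least 1.5, and their split turned to 140 higher and 272 lower. In all, 94 probe sets were in both the 356 and the 412. The count of 356 went to 1108 without control replicate 1, 98 without BL replicate 1 and 147 without BL replicate 2.

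The gene with the smallest p was AT1G54890, at 7.86 ± 0.0482 with BL (SD, n = 2) and 5.72 ± 0.0744 in controls (SD, n = 3). Its log2 difference was 2.14 ± 0.0928 (SE), and its limma adjusted p after Benjamini-Hochberg was 0.168. AT4G30650 had the widest difference among the 12 named genes on the higher side, 3.6 ± 0.264, which is a fold of 12.1. ATMYC1, a basic helix-loop-helix transcription factor of epidermal cell fate, stood at 3.79 ± 0.0168 in controls and 5.27 ± 0.182 with BL, a difference of 1.48. Its control mean, like those of AT4G30650 and AT5G43040, lay below the median of every array. How far such values lie over background was not analysed. AT3G27473, AT4G14980 and AT5G43040, which encode proteins with C1 domains, differed by 1.74, 1.09 and 2.66. AT1G31950, of the terpene synthase family, differed by 2.94, the cytochrome P450 gene CYP718 by 1.74, and AT5G11000 by 1.07. The limma adjusted p values of these 12 genes ran from 0.168 to 0.475.

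Among the 12 named genes on the lower side, the lipid-transfer-protein type genes AT5G05960 and AT1G48750 differed by -2.02 ± 0.176 and -2.04 ± 0.237. AT1G48750 was at 11.7 in controls and 9.69 with BL. AT1G10140 differed by -1.39, AT3G28940 by -1.27, the MYB-like transcription factor gene AT1G69580 by -1.06, and the leucine-rich-repeat kinase gene AT5G14210 by -1.17. AT5G04750 and AT5G08350 differed by -0.75 and -0.84. CHLM, an enzyme of chlorophyll synthesis, differed by -0.77. The limma adjusted p values of these 12 genes ran from 0.25 to 0.548. All 24 genes kept their sign within the batch, where the differences ran from 1.05 to 3.70 and from -2.91 to -0.75. The rule picked genes whose control arrays lay close together, control replicate 1 included, so a shared sign is what the choice alone would give.

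**Figure D2:**
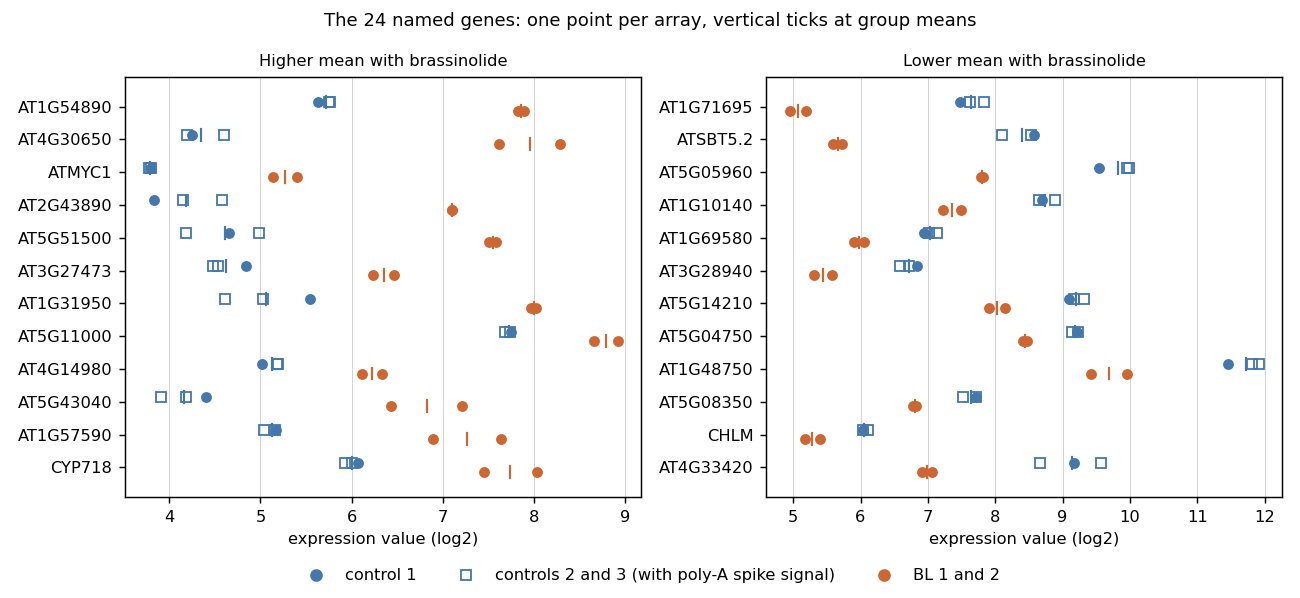
Log2 expression values of the 24 named genes, 1 point per array, with controls in blue (open squares for replicates 2 and 3, which carried poly-A spike signal), BL arrays in orange and short vertical lines at the group means. BL and control points of each gene are apart because the rule asked for that, and none of the 24 differences passed the adjusted test (smallest adjusted p 0.168).

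Brassinosteroid genes were mostly outside the annotation used here. Of the 323 members of the 23 gene lists, 40 have a probe set that names a single gene, and 4 lists had 3 or more of them. Of the 14 genes that were to be named whatever their value, only BRL1, a receptor related to BRL3, had such a probe set, and the other 13 were not analysed here. BRL1 was at 5.90 ± 0.196 with BL (SD, n = 2) and 5.20 ± 0.949 in controls (SD, n = 3). Its difference of 0.70 ± 0.608 (SE) was 0.21 within the batch and did not pass (limma adjusted p = 0.810). BAT1, an acyltransferase that inactivates brassinosteroids, was the only measured member of the inactivation list, at 7.67 with BL and 9.30 in controls. Its difference of -1.62 ± 0.5 was -2.16 within the batch. BAT1 passed adjusted over the list alone, where with 1 measured member no adjustment is made, and did not pass over all genes (limma adjusted p = 0.653).

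Hormone lists held few measured genes. In the auxin list 1 of 6 members had a higher mean with BL and 5 a lower one, with a median log2 difference of -0.61, and 0 passed over all genes or adjusted over the list alone. LBD29, which acts in lateral root initiation, differed by -0.65 ± 0.283, and IAA29, an auxin response repressor, by -0.57 ± 0.379, which were -0.86 and -0.78 within the batch. In the list of BL-induced growth genes 4 of 5 members had a higher mean, with a median of 0.27 that was -0.12 within the batch. The expansin gene EXPA8 differed by 0.68 and ARL, which promotes organ growth, by 0.56, against 0.53 and -0.12 within the batch. COR47 and COR15A of the abscisic acid list differed by 0.59 and 0.07, which were 0.15 and 0.10 within the batch. EIN3 of the ethylene list differed by 0.63, which was 0.26 within the batch. RR16 and ARR15 of the cytokinin list differed by -0.06 and 0.02, which were -0.0093 and 0.07 within the batch. None of the members named here for these lists passed adjusted over the list alone.

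Genes of the root stem cell niche and of vascular tissue gave a similar picture of small numbers. In the stem cell niche list 4 of 5 members had a higher mean with BL, among them JKD at 0.47 and BBM at 0.58 (0.48 and 0.98 within the batch), with a list median of 0.45 that was 0.03 within the batch. In the vascular list, PHV, a transcription factor of vascular patterning, differed by -0.87 ± 0.238 (-0.56 within the batch) and OPS, a phloem regulator, by -0.07, which turned to 0.08 within the batch. The limma camera test called none of the 4 lists with 3 or more measured members. Its adjusted p was 0.304 for each with a preset correlation and 0.407 with an estimated correlation. By fry, too, none of the 4 was called (adjusted p 0.461 to 0.531). The vascular median was -0.07 and its mean -0.28. Without BL replicate 2 the auxin list passed, with a median of -0.94 and a camera adjusted p of 0.035, so that array decides this call.

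Of the cell cycle lists, 2 of 20 members for G2 and mitosis, 1 of 14 for S phase and 1 of 13 for inhibitors and D-type cyclins were measured, too few for a test of any of them. AUR1 and AUR2, mitotic Aurora kinases, differed by -1.13 ± 0.366 and -0.44 ± 0.253, and PRL, a subunit of the replication licensing complex, by -0.71 ± 0.283. Within the batch these were -0.65, -0.31 and -0.21. SIM, a cell cycle inhibitor, differed by -0.22, which turned to 0.33 within the batch. None of these genes passed adjusted over its list alone.

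STZ, a zinc finger transcription factor of stress responses, was at 10.1 ± 0.203 with BL (SD, n = 2) and 11.4 ± 0.342 in controls (SD, n = 3). It passed adjusted over the list alone in the list of stress and protoplasting response, which had 2 measured members, and did not pass over all genes (limma adjusted p = 0.560). Its difference was -1.36 ± 0.245 and -1.75 within the batch. WRKY53, the other member, differed by -1.10 ± 0.436 and by -1.85 within the batch.

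Markers of other root cell types and reference genes showed no call. CO2, a cortex marker, was at 3.83 with BL and 3.84 in controls, with a difference of 0.37 within the batch. The hair cell expansins EXPA7 and EXPA18 differed by -0.27 and 0.14, against 0.57 and 0.85 within the batch. COB and EXPA4 of the cell wall synthesis list differed by -0.72 and 1.04, which were -0.17 and 0.07 within the batch. RCA, an abundant leaf transcript, was at 4.57 with BL and 4.79 in controls. The reference genes SAND and TIP41 differed by -0.43 and -0.12, which were -0.01 and 0.07 within the batch. The lists for brassinosteroid biosynthesis, BL-repressed transcription factors, gibberellin, jasmonate and the root cap had no member with a single gene name and were not analysed here.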

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

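The term for controls 2 and 3, the fit without them and the exclusion of probe sets without residual spread were chosen after seeing the data, and the other alternatives before. The count of 0 adjusted calls held in all alternatives, with the smallest adjusted p at 0.057 under array weights, except that the ordinary linear model called 1 when probe sets without residual spread were tested. The 24 genes named by the first part of the rule kept their direction in all 451 alternatives and passed in 0. The rule asked for BL values on 1 side of all control values. Leaving out, weighting or blocking arrays could therefore not reverse a sign, and other variance models leave the difference itself unchanged. The kept direction is thus mostly fixed by the choice of genes. Over all 53 named genes, these 24 included, 957 of 987 alternatives kept the direction. The count of 356 at an unadjusted p under 0.01 and a fold of 1.5 became 237 above the median level, 236 with a floor, 907 with array weights, 118 in the ordinary model, 634 without controls 2 and 3, 1212 at p under 0.05, 220 at a fold of 2, and 98 to 1108 with 1 array left out. Fewer probe sets, fewer arrays or other thresholds enter several of these by construction, and for the rest the cause was not tested.

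Deviations from the group means correlated at -0.060 for both replicates 1 and 0.037 for both replicates 2. The deviations of the 2 BL arrays mirror each other by construction. BL replicate 2 with control replicate 1 thus gave 0.060, and BL replicate 1 with control replicate 2 gave -0.037. These values cannot show whether a replicate number marks a shared batch of seedlings. With the replicate block the count was 199, of which 76 were among the 356, and the adjusted count stayed at 0. The block turned COR15A to -0.019, EXPA18 to -0.058, OPS to 0.038 and the vascular median to 0.038.

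With the term for controls 2 and 3, and equally without these arrays, ARL turned to -0.12, SIM to 0.33, CO2 to 0.37, EXPA7 to 0.57, TIP41 to 0.074, OPS to 0.075 and the median of the BL-induced growth genes to -0.12. CO2 turned to 0.040 with quantile normalization, 0.042 with cyclic loess and 0.063 with array weights, and EXPA7 to 0.15 with array weights. With 1 array left out, where a lone BL array is assumed to vary like the controls, values of both signs arose: COR15A from -0.019 to 0.17, SIM from -0.50 to 0.094, CO2 from -0.19 to 0.22, ARR15 from -0.0095 to 0.037, EXPA7 from -0.68 to 0.48, EXPA18 from -0.21 to 0.70, TIP41 from -0.21 to 0.039, OPS from -0.14 to 0.038 and the vascular median from -0.15 to 0.038. The auxin median ran from -0.94 without BL replicate 2, past the threshold, to -0.29 without BL replicate 1. None of these single genes was called, and the cause was not tested. The 3' minus 5' difference ran from -0.14 to 0.01. How far signal lies over background was not analysed here.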

Other observations

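The gene families and organelle groups of this part, the within-batch test of the pectin and peroxidase genes and the tests on chloroplast, mitochondrial and nuclear photosynthesis genes were chosen after seeing the data. The tests on disjoint arrays, on other splits and on the pectin and peroxidase classes were written down before their results were seen, but they are read here by stricter criteria set after their results were known. Bounds now have to be cleared by more than the interval, a missed p excludes nothing, and a test whose outcome is fixed by the choice of genes or by components that cancel decides nothing. Each interval in this part comes from resampling probe sets or genes, as if independent, on the same arrays. It holds no variation between arrays, so it is too narrow as a measure of what other arrays would give. By the bounds as first written, the disjoint-array tests and both class tests would have counted against their explanations, and so would 2 of the tests chosen later, on the 4 named genes and on green tissue.

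Among 30 families read from gene symbols, limma camera with a preset correlation gave an adjusted p of 0.0125 for 47 UGT glycosyltransferases (28 higher and 19 lower with BL, median 0.13) and for 11 GSTU glutathione transferases (8 higher and 3 lower, median 0.09), both upward. With an estimated correlation the adjusted p was 0.763 for each, so neither passed in that form. There 0.763 was the smallest camera adjusted p of all 30 families. For UGT the estimated correlation was 0.0093, close to the preset 0.01, while the unadjusted camera p went from 0.0015 to 0.0488. The estimated form uses the 3 residual degrees of freedom, so with 30 families it could hardly call any and does not decide. By fry the adjusted p was 0.356 for both UGT and GSTU. GSTU20 differed by 2.77 (1.69 within the batch), GSTU25 by 1.5 (1.0) and GSTU22 by 1.36 (1.05). UGT73B5 differed by 2.16 (1.57) and UGT71B1 by 1.23 (1.27). These members were named after their values were seen, and none passed over all genes. With the batch term, camera called none of the 30 families (adjusted p 0.709 for UGT and 0.338 for GSTU). The 2 measured root hair genes were EXPA7 and EXPA18.

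The first pattern is the difference between BL and control arrays over all probe sets. A quality gradient running from control replicate 2 over control replicate 3 to the BL arrays would make the BL mean minus control replicate 1 follow control replicate 3 minus control replicate 2, and these correlated across probe sets at 0.0430 (bootstrap interval 0.0186 to 0.0666), but the first component contributed with a positive sign and the second, which sets control replicate 3 apart, cancelled it, so a gradient stays open. Of the 10 splits of the 5 arrays, 2 gave at least 356 probe sets, the real one with 356 and 1 other, and that other, with 1188 and 7 adjusted calls, set controls 2 and 3 against the rest and so follows the spike batch, a structure of the samples; 10 splits are too few for a share under 0.05, and the within-batch count was 412. If that batch were the whole cause, BL differences taken from disjoint arrays should correlate at 0.1 or less, and the lower of 2 such values was 0.30 (interval 0.283 to 0.319), which is above the bound of 0.3 set beforehand and would by that alone count against the batch, but not by more than its interval, a demand added after the value was seen. That value rests on control replicate 1 alone, and 4 of 54 arrangements that do not set BL against control gave as much, up to 0.352, each with controls 2 and 3 against other arrays, so the batch and an effect of BL cannot be told apart.

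The second pattern is the higher values of pectin-modifying genes and lower values of class III peroxidase genes among the named genes. At an unadjusted p under 0.05, 10 of 107 measured pectin genes were higher and 0 lower, the named ones included, and 4 passed adjusted over the list alone, all higher, on a list drawn up after seeing the data; of 55 peroxidase genes 2 were higher and 2 lower, the latter being the named ones and both passing adjusted over the list alone, and AT4G11290, named here after its value was seen, was higher by 3.17 (2.20 within the batch). For the full pectin list (49 higher, 58 lower, median -0.03, mean 0.19) the camera adjusted p was 0.342. It was 0.673 with an estimated correlation, and the peroxidase list had the same adjusted values (19 higher, 36 lower). Many pectin genes had low values and small differences, such as ADPG1 (3.44 in controls, difference -0.15) and AT2G02720 (3.75, 0.03). The split and the median therefore do not show a balanced response. By fry the adjusted p for a shift in a common direction was 0.391 for each list. For changes in either direction its unadjusted p was 9.4e-05 for pectin and 0.0355 for peroxidase genes, on lists drawn up after seeing the data. Without the named genes the camera p was 0.574 for the pectin list (105 genes) and 0.792 for the peroxidase list (53 genes), and as a p that misses the threshold on a list without its leading genes excludes nothing, class-wide effects of BL stay open. The 4 named genes differed by a median size of 2.65 within the batch, but 100% of the 356 probe sets kept their sign there by the way they were picked, so this cannot exclude the spike batch.

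The third pattern is that all 69 chloroplast-encoded transcripts had lower means with BL. Their median difference was -1.01, with a camera adjusted p of 8.3e-07. With the estimated correlation of 0.945, as these genes move together, the unadjusted camera p was 0.438. The adjusted p of 0.763 in that form is a value shared with other families, such as UGT, and so does not measure this correlation. The chloroplast-encoded medians were 9.31 in control replicate 2 and 6.64 in control replicate 3. In control replicate 1 and BL replicates 1 and 2 they were 5.93, 6.08 and 5.65. Within the batch the median difference was -0.052. The spike batch alone would give this, but so would any other cause that acts on control replicate 2 or 3 alone. The value therefore does not single out the batch, as both arrays carried poly-A spike signal but had unlike chloroplast-encoded medians. Mitochondrion-encoded genes were also higher in controls 2 and 3, by a median of 0.82 (15 of 16 genes), which is in line with labelling that favoured organelle transcripts, although control replicate 3, at 6.27, did not exceed BL replicate 1, at 6.28. Green tissue would also raise nuclear photosynthesis genes. In control replicate 2 the chloroplast-encoded median was higher by 2.69 than on the 3 arrays without poly-A spike signal. There the median of the nuclear genes was higher by 0.15 (19 genes, interval -0.0033 to 0.57). For the 4 above the median level it was higher by 0.73 (interval 0.63 to 1.07). Against control replicate 1 alone, the same medians were 2.84 for chloroplast-encoded genes, 0.07 for the 19 and 0.27 for the 4. Of these 4, PGRL1B and PSBW were higher and LHCB4.1 and ATPC1 lower. The nuclear genes thus rose by less than the chloroplast-encoded ones, which by the bound chosen after seeing the data counts against green tissue there. But 15 of the 19 lie below the median level, and how far they lie over background was not analysed. With 4 brighter genes on a single array, these values do not decide. Over controls 2 and 3 together the nuclear photosynthesis genes were higher by a median of 0.19 (14 of 19 genes, interval 0.01 to 0.26). For control replicate 3, where the chloroplast-encoded median was higher by only 0.40, green tissue stays open as well.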
